A study of Oryctolagus cuniculus with 16 samples.

How the data were processed

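RNA was measured in 16 libraries from the tibiae of 4 rabbits, taken 10 days after surgery. Each rabbit gave 1 library per group (Sham, Turned Ti, SLA Ti and Turned Cu), and the replicate number is the rabbit, so that the 4 replicates of a group are separate animals. Per the labels, implants were removed, tissue was scraped from the wall of the hole with a curette, and RNA was extracted with TRIzol and treated with DNase. Libraries were made with a stranded total RNA kit and read as pairs of 75 bp on an Illumina HiSeq instrument. STAR 2.7.1a and Cufflinks 2.2.1 are named in the submitters' processing notes, which do not say how the gene counts were made. The genome build is not given in the sources used here, and gene coordinates are printed as the gene table states them.

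The gene table deposited by the authors holds 29587 Ensembl rabbit genes. Its deposited read counts are whole numbers and were taken as estimated counts, because some genes at a count of 0 have an RPKM above 0. Per the file headers the same table holds RPKM values, in which counts are divided by transcript length and library size. It also holds, per the file headers, the authors' log2 fold changes with a p-value and a q-value for each of their comparisons, without a stated test. Numbers of genes past thresholds come from the authors' deposited summary table, and their calls were recomputed from the gene table as a p under 0.05 with at least a 2-fold change. Transcript-level counts in the deposited summary were not used here. All values reported for genes and lists come from the counts, and RPKM served to work out relative transcript lengths.

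Of the genes in the file 14537 carry a symbol. A further 69 were named from a RefSeq description that matched 1 gene and 22 from a full gene name, and 14959 stayed without a name. None of the identifiers occurred in the RefSeq table at hand, so unnamed genes were tested but are not named. Metallothioneins, CC chemokines and ferritins have near-identical relatives whose reads are hard to assign, and the gene model of ATOX1 overlaps SPARC.

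Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 11617 genes (8904 with a name). Library sizes were scaled by TMM factors over all kept genes. A quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, which share 1 estimate of the spread (common dispersion 0.206). Each pair of groups was compared with the two-sided quasi-likelihood F test and p-values were adjusted by Benjamini and Hochberg within the comparison, with a threshold of 0.05. SE of a gene is the absolute log2 fold change over the square root of F. CPM are taken of the scaled library size. For a gene without a read in a group, a lower bound of the fold was worked out against a floor of 3 counts over the group.

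Gene lists for cell types, tissues and pathways were written before the data were examined, 47 in all, and 43 had at least 5 tested members. Members without a name or removed by the filter were not tested. This left 8 of 16 osteoclast genes, 6 of 22 T cell genes and 5 of 25 skeletal muscle genes, among others. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.010, with camera at an estimated correlation and with fry, each adjusted by Benjamini and Hochberg over the lists. Numbers of members past the test are given over all genes and adjusted over the list alone. Principal components were computed from log2 CPM (prior count 2) of the 500 most variable genes.

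Genes are named by a rule fixed before the data were examined. It admits, for each comparison, up to 12 genes with the highest and 12 with the lowest log2 fold change among those past the threshold, or the 6 genes of smallest p where none passed. It also admits up to 4 members of smallest p for each list described. ALPL, RUNX2, SP7, IBSP, BGLAP, CTSK and the metallothionein and copper transporter genes may be named whatever their p. The rule also held ACP5, which had no symbol here and could not be looked up. Other genes named in the text were chosen after their values were seen.

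Library totals ran from 8539984 to 20406474 counts, and counts on protein-coding genes outside the mitochondrial genome from 965804 to 3960681. Chi-square per degree of freedom between replicates was 53.8 to 1195 over the kept genes, ribosomal RNA and mitochondrial genes among them. Replicates thus differed by more than counting alone gives. They differ in rabbit, site position and share of ribosomal RNA, which this value does not tell apart. It also does not measure counting noise in genes with few reads. In all, 0 pairs of libraries were identical. The pipeline was tested on simulated data, in which changed genes were planted among counts of the same spread. Of 10574 to 11101 simulated genes tested per comparison, 91 to 99 were changed at each fold. A 4-fold change was called for 38.9% to 57.1% of planted genes over the 6 comparisons and a 2-fold change for 1.02% to 5.38%. With few changed genes the adjustment for multiple tests is strict. These shares therefore do not carry over to the copper comparisons, where 3598 to 4968 genes passed.

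Samples of 1 rabbit are paired by design. The correlation of residual log2 CPM, after subtracting group means, averaged 0.0856 over 24 pairs of libraries from 1 rabbit (-0.167 to 0.316, 12 above 0.1) and -0.0283 over 72 pairs from different rabbits. The model without a block was fixed before the data were examined, with the rabbit as a block, alone and with the site position, as alternatives.

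Other alternatives fixed before the data were examined were no filter beyond dropping genes at 0 everywhere, a group mean of at least 5 CPM, DESeq2 1.42.0, voom with library quality weights, the dispersion without an abundance trend, the libraries of the compared groups alone, a fold change of at least 2 with an unadjusted p under 0.05, and leaving out each library or each rabbit in turn. Chosen after seeing the data were RLE scaling in edgeR, leaving out ribosomal RNA and mitochondrial genes, thinning to equal depth (equal totals over genes that are neither ribosomal RNA nor mitochondrial, which alone were tested), leaving out the 4 libraries richest in nuclear ribosomal RNA, leaving out Turned Ti replicate 1 and SLA Ti replicate 3 together, and taking Turned Cu replicates 2 and 4 as the copper group. For every comparison the 35 splits of its libraries into groups of 4 and 4 were tested the same way, with the other libraries in place.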

Results

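Total RNA from rabbit tibiae was sequenced 10 days after surgery, to follow how bone tissue responds to implants that differ in metal and surface. Each of 4 rabbits carried 4 drilled sites, at the proximal and distal end of the right and left tibia. A site was labelled Sham or received a turned implant of commercially pure titanium (Turned Ti), a sandblasted and acid-etched titanium implant (SLA Ti) or a turned copper implant (Turned Cu). Every rabbit had all 4 kinds of site and each kind of site took each position once, so each group held 4 libraries from separate animals. Tissue was scraped from the wall of the drilled hole, so that the RNA came from a mixture of cell types. Totals over all genes ran from 8539984 read counts in Turned Cu replicate 3 to 20406474 in Turned Cu replicate 2. Much of this was ribosomal RNA. Counts on protein-coding genes outside the mitochondrial genome ran from 965804 in Sham replicate 2 to 3960681 in Turned Ti replicate 1. Levels below are CPM (counts relative to the scaled library size) as mean ± SD over 4 libraries. Differences are log2 fold changes ± SE, negative where the first-named group was lower, from edgeR's fit with n = 4 libraries per group. For gene lists the adjusted p of camera at a preset correlation is followed by its adjusted p at an estimated correlation.

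The Turned Cu libraries stood apart from all others. On the first principal component of the 500 most variable genes, which held 67.5% of their variance, the Turned Cu libraries lay between 69 and 79. The Sham, Turned Ti and SLA Ti libraries lay between -44 and 17, with SLA Ti replicate 3 nearest to copper. Nuclear ribosomal RNA made up 65.3% of counts in Sham replicate 2, 49.6% in Turned Ti replicate 4 and 44.8% in SLA Ti replicate 4, and no more than 28.4% elsewhere. Transcripts of the mitochondrial genome took 74.1% of the counts outside ribosomal RNA in Turned Cu replicate 2 and 65.5% in Turned Cu replicate 4, against 12.1% to 39.6% in the other libraries. Between 7445 and 8362 genes reached 10 counts in a Turned Cu library, and between 8320 and 11358 in the others.

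**Figure D1:**
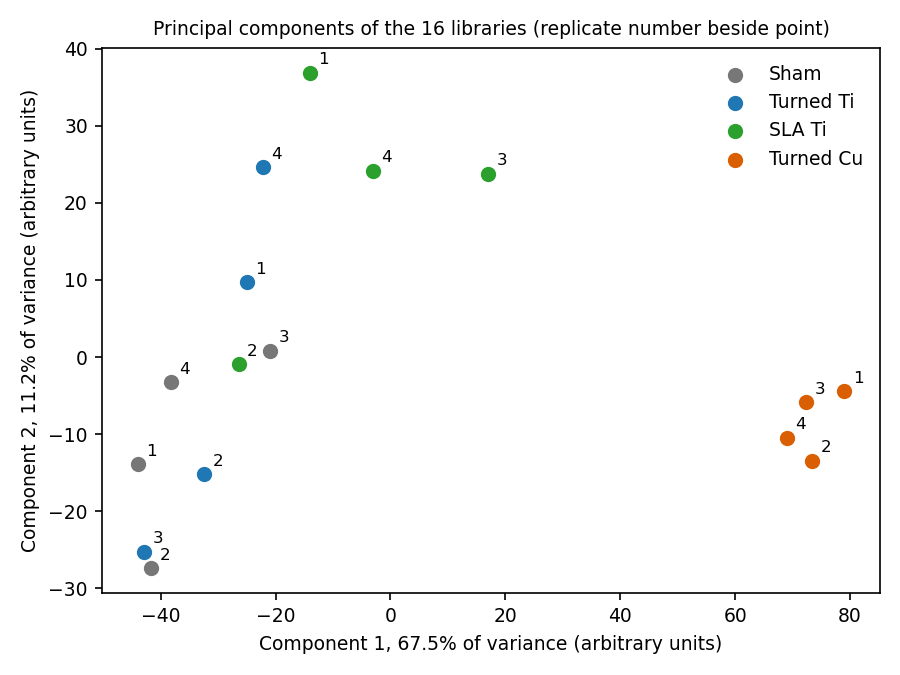
First and second principal component (arbitrary units) of log2 CPM of the 500 most variable genes, 1 point per library, coloured by group. The Turned Cu libraries lie between 69 and 79 on the first component and the other libraries between -44 and 17.

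**Figure D2:**
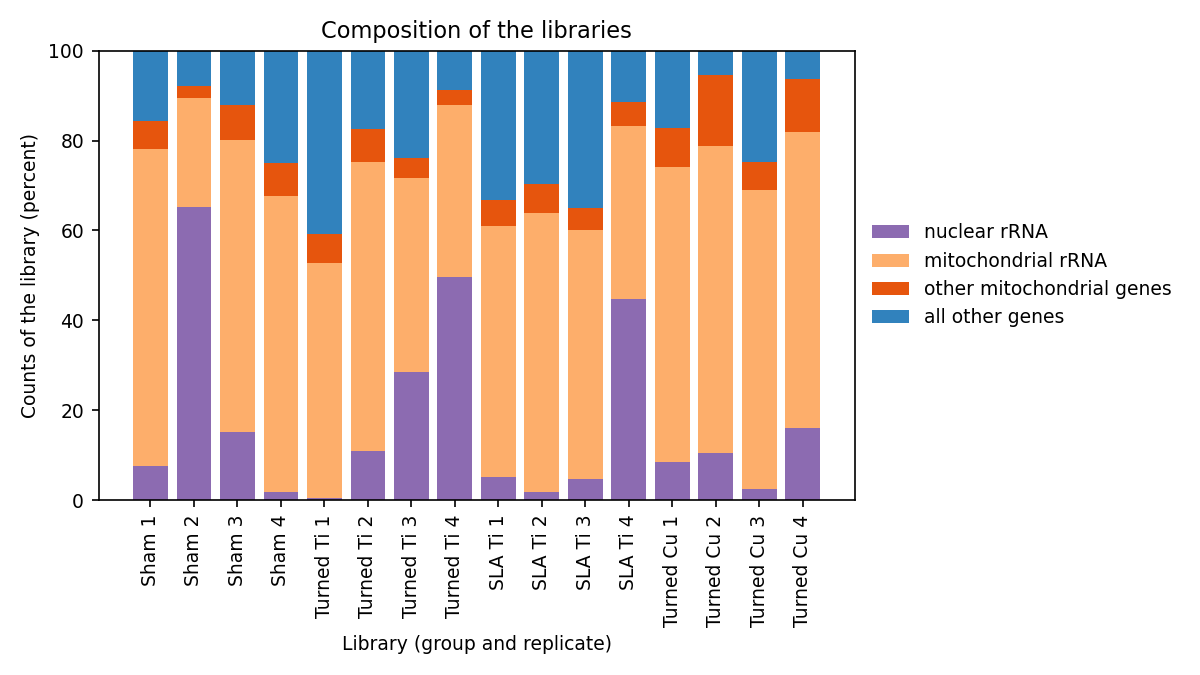
Percent of each library's counts on nuclear ribosomal RNA, mitochondrial ribosomal RNA, other mitochondrial genes and all other genes, as stacked bars, 1 bar per library. Sham replicate 2 holds 65.3% nuclear ribosomal RNA, and other mitochondrial genes reach 15.7% in Turned Cu replicate 2.

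The comparison of Turned Cu with Sham asks which transcripts differ beside a copper implant. Inflammatory mediators rose and transcripts of bone, connective tissue and vessel wall fell. CXCL8, a chemokine that draws in neutrophils (ENSOCUG00000011835, chromosome 15, 76368959 to 76371691), stood at 2303 ± 769 CPM in Turned Cu and 1.24 ± 1.17 in Sham, a log2 fold change of 10.86 ± 1.90. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 9.44 ± 1.42, and IL1B, the cytokine interleukin 1 beta, by 8.62 ± 1.69. DESeq2 gave no p for CXCL8 and IL1B because of their extreme count in SLA Ti replicate 3. COL1A2, a chain of type I collagen (ENSOCUG00000012264, chromosome 10, 34497959 to 34533850), fell from 9339 ± 3777 CPM in Sham to 425 ± 456 in Turned Cu, a log2 fold change of -4.46 ± 0.84. Of 11617 genes tested, 4968 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2695 higher and 2273 lower in Turned Cu. The larger of the 2 numbers turned with the scaling: 2405 were higher and 2718 lower by RLE scaling. They were 2541 and 2974 by DESeq2, and 2411 and 2710 without ribosomal RNA and mitochondrial genes. It also turned without any 1 of the Turned Cu libraries or without Sham replicate 1, 3 or 4, to between 2103 and 2403 higher and between 2422 and 2706 lower.

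Of the list of inflammatory cytokines and chemokines, 10 of 12 tested members rose and 2 did not pass (11 rose adjusted over the list alone, camera adjusted p = 6.00e-06, estimated 0.185). CCL4, a chemokine for monocytes and T cells, rose by 10.51 ± 1.66, TNF by 6.44 ± 1.07 and IL1RN, the antagonist of the interleukin 1 receptor, by 7.99 ± 1.15. IDO1, a tryptophan-degrading enzyme induced by interferon, rose by 8.96 ± 1.66. For IL1A, IL22RA2, PTPRN, IL-15L and FSD2 no read was counted in the Sham libraries. Against a floor of 3 counts over the group these genes were at least 62.9-fold, 97.7-fold, 146-fold, 92.1-fold and 78.9-fold higher in Turned Cu. Without Sham replicate 4 these bounds fell to 39, 60.5, 90.7, 57.1 and 48.9, and without Turned Cu replicate 3 to 86.9 for PTPRN and 45.1 for FSD2. Of the interferon response genes, 11 of 15 tested members rose and 4 did not pass (12 rose adjusted over the list alone, camera adjusted p = 2.32e-05, estimated 0.17), with RSAD2 at 6.64 ± 0.84 and the transcription factor IRF1 at 4.54 ± 0.59. Among antigen presentation genes, 10 of 12 tested members rose and 2 did not pass (11 rose adjusted over the list alone, camera adjusted p = 3.59e-05, estimated 0.101), led by B2M, the light chain of MHC class I, at 5.37 ± 0.73 (no p by DESeq2, for the same library) and the peptide transporter TAP1 at 4.93 ± 0.80. CC chemokines and MHC genes belong to families of similar sequence, so counts of single members are uncertain.

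Markers of phagocytes moved in part. In the neutrophil list 7 of 12 tested members rose and 5 did not pass (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0732, estimated 0.74), with CSF3R, the receptor for granulocyte colony-stimulating factor, at 5.72 ± 1.26. In the macrophage list 7 of 13 tested members rose and 6 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.0838, estimated 0.436), with CD68 at 3.96 ± 0.61, CD14 at 3.45 ± 0.54 and the scavenger receptor MSR1 at 3.38 ± 0.56. CSF1, the growth factor of the macrophage and osteoclast lineage, rose by 4.79 ± 0.46. In its list, the osteoclast regulators, 1 of 5 tested members rose and 4 did not pass (1 rose adjusted over the list alone, camera adjusted p = 0.665, estimated 0.793). The median log2 fold change of that list was -1.11. In the osteoclast list 1 of 8 tested members rose and 7 did not pass (1 rose adjusted over the list alone, camera adjusted p = 0.783, estimated 0.92). The member that rose was CA2, carbonic anhydrase 2, at 1.71 ± 0.53, which no longer passed without Turned Cu replicate 2 or 4 (0.90 and 1.40) or Sham replicate 3 (1.22). CTSK, the collagenase cathepsin K, stood at 321 ± 100.3 CPM in Turned Cu and 180.3 ± 143 in Sham (0.83 ± 0.66, not past the test).

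Most bone and connective tissue genes fell. In the osteoblast and bone matrix list 14 of 15 tested members fell and 1 did not pass (14 fell adjusted over the list alone, camera adjusted p = 4.18e-06, estimated 0.246). ALPL, the phosphatase of mineralizing cells (ENSOCUG00000004447, chromosome 13, 131692107 to 131706214), fell from 43 ± 14.3 to 1.19 ± 1.84 CPM (-5.07 ± 0.97), the osteoblast transcription factor SP7 changed by -4.13 ± 0.96 and RUNX2, which acts before it, by -1.76 ± 0.41. The matrix proteins IBSP and BGLAP changed by -3.75 ± 1.18 and -4.24 ± 1.39, and BGLAP no longer passed without Turned Cu replicate 1, 2 or 4 (-3.94, -3.97 and -3.95). In the fibroblast and extracellular matrix list 15 of 17 tested members fell and 2 did not pass (15 fell adjusted over the list alone, camera adjusted p = 1.17e-07, estimated 0.185), with the proteoglycans BGN at -2.75 ± 0.34 and DCN at -2.80 ± 0.45, tenascin TNC at -4.31 ± 0.61 and the growth factor receptor PDGFRA at -3.71 ± 0.50. The cartilage list had ACAN, the aggregating proteoglycan, at -6.82 ± 1.14 but MATN1 at 3.73 ± 0.53, and 1 of 10 tested members rose, 7 fell and 2 did not pass (1 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.021, estimated 0.455). Of the BMP and TGF-beta signalling genes 1 of 14 tested members rose, 9 fell and 4 did not pass (1 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.00734, estimated 0.215), with TGFB3 at -5.002 ± 0.58 and the receptor BMPR1A at -4.02 ± 0.58, while ID2 rose by 3.90 ± 0.76. Of the Wnt signalling genes 7 of 12 tested members fell and 5 did not pass (8 fell adjusted over the list alone, camera adjusted p = 0.00608, estimated 0.215), with the receptors FZD1 at -3.47 ± 0.40 and LRP6 at -2.15 ± 0.41.

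Vessel and perivascular genes also fell for the most part. In the endothelial list 2 of 11 tested members rose, 8 fell and 1 did not pass (2 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.00119, estimated 0.185). CDH5, the cadherin of endothelial junctions, stood at -4.06 ± 0.50 and the angiopoietin receptor TEK at -5.83 ± 0.91, while PECAM1, which leukocytes and platelets also carry, rose by 4.004 ± 0.65. STAB2, a scavenger receptor of sinusoidal endothelium, had 1631 counts in Sham and none in Turned Cu, at least 201-fold lower against the floor of 3 counts over the group (110.0-fold without Sham replicate 1). CLEC14A, another endothelial gene, was at least 26.9-fold lower. In the smooth muscle and pericyte list 8 of 10 tested members fell and 2 did not pass (9 fell adjusted over the list alone, camera adjusted p = 0.000106, estimated 0.185), with PDGFRB at -3.22 ± 0.41 and NOTCH3 at -2.84 ± 0.48. Of the angiogenesis genes 1 of 11 tested members rose, 6 fell and 4 did not pass (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0334, estimated 0.185), with the apelin receptor APLNR at -4.75 ± 0.72. Adipocyte genes included the adipokine ADIPOQ at -5.83 ± 0.88, and 3 of 8 tested members fell and 5 did not pass (3 fell adjusted over the list alone, camera adjusted p = 0.0334, estimated 0.493).

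Metallothionein and stress genes rose beside copper. The metallothioneins, small proteins that bind copper and zinc, went from 6.12 ± 2.25 to 152 ± 50.8 CPM for MT1A (4.63 ± 0.47, ENSOCUG00000029235, chromosome 5, 12927625 to 12936574) and from 1.21 ± 1.61 to 31.1 ± 6.66 CPM for MT2A (4.63 ± 0.82), though reads could be divided between these near-identical genes. HMOX1, the haem-degrading oxygenase (ENSOCUG00000010633, chromosome 4, 86061604 to 86066620), rose by 5.73 ± 0.74, and the thioredoxin reductase TXNRD1 by 3.10 ± 0.35. In the oxidative stress list 13 of 16 tested members rose, 2 fell and 1 did not pass (13 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.65e-05, estimated 0.101). In the heat shock and unfolded protein list 9 of 14 tested members rose and 5 did not pass (9 rose adjusted over the list alone, camera adjusted p = 0.00016, estimated 0.101), with the chaperone HSP90AA1 at 2.63 ± 0.33 and the stress factor DDIT3 at 4.77 ± 0.78. The copper handling list was not called as a whole, and 6 of 17 tested members rose, 3 fell and 8 did not pass (6 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.80, estimated 0.91). Of the copper pumps ATP7B changed by -3.40 ± 0.72 and ATP7A by 1.18 ± 0.46. ATP7A no longer passed with the rabbit as a block (1.12), without Sham replicate 1, 3 or 4 (0.93, 0.86 and 0.91) or without Turned Cu replicate 1, 2, 3 or 4 (1.07, 1.12, 0.68 and 1.19). The importer SLC31A1 had a value of -0.76 ± 0.86 that did not pass. The chaperone ATOX1 stood at -3.97 ± 0.50, with a gene model that spans SPARC, a matrix gene, itself at -3.83 ± 0.58.

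Genes of sugar breakdown and rapid transcriptional response rose as well. In the glycolysis and hypoxia list 15 of 19 tested members rose and 4 did not pass (15 rose adjusted over the list alone, camera adjusted p = 6.00e-06, estimated 0.244), with pyruvate kinase PKM at 3.61 ± 0.47 and the glucose transporter SLC2A1 at 3.08 ± 0.49. In the immediate early list 11 of 13 tested members rose and 2 did not pass (11 rose adjusted over the list alone, camera adjusted p = 4.18e-06, estimated 0.101), with ZFP36, which destabilizes cytokine messages, at 6.11 ± 0.91 and EGR1 at 4.13 ± 0.72. In the mitochondrially encoded list 11 of 13 tested members rose and 2 did not pass (13 rose adjusted over the list alone, camera adjusted p = 0.00839, estimated 0.651), with ND5 at 2.35 ± 0.66, and the level was 13.93 and 13.34 in Turned Cu replicates 2 and 4 but 11.66 and 10.58 in replicates 1 and 3, against 10.09 to 11.30 in Sham. Of the cell death genes 6 of 11 tested members rose, 1 fell and 4 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0127, estimated 0.215), with the pore-forming GSDMD at 4.11 ± 0.46. In the list of common housekeeping genes 5 of 6 tested members rose and 1 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.00616, estimated 0.185). In the pro-inflammatory macrophage list 5 of 9 tested members rose and 4 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.00301, estimated 0.17). Of 43 lists tested, camera with a preset correlation called 20 and fry 26, while with an estimated correlation the lowest adjusted p of camera was 0.101.

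**Figure D3:**
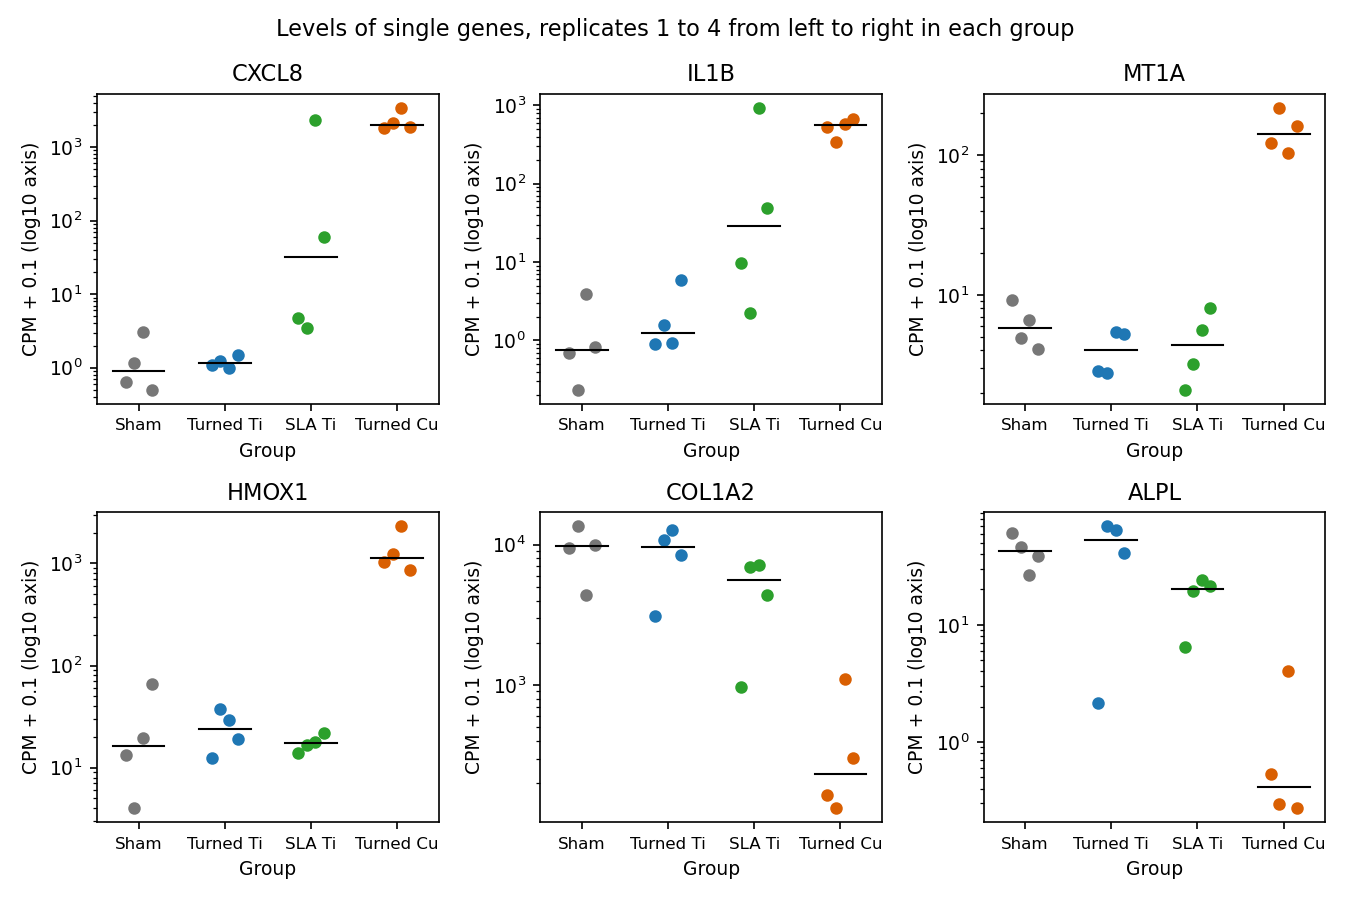
CPM on a log10 axis (CPM + 0.1) of CXCL8, IL1B, MT1A, HMOX1, COL1A2 and ALPL, 1 point per library and a bar at the group median, for Sham, Turned Ti, SLA Ti and Turned Cu. SLA Ti replicate 3 has 2329 CPM of CXCL8 and 17.8 of HMOX1, and the lowest Turned Cu library has 854 CPM of HMOX1.

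**Figure D4:**
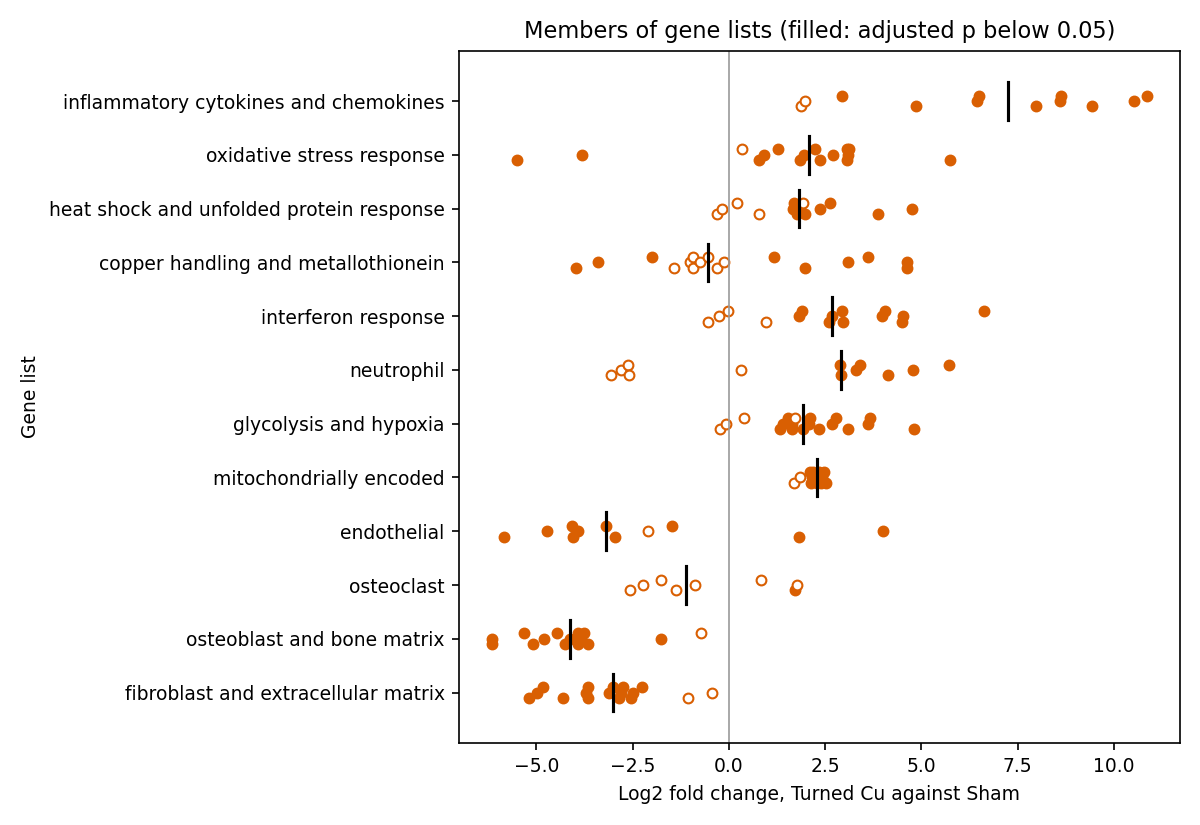
Log2 fold change of each tested member of 12 gene lists in Turned Cu against Sham, 1 point per gene, filled where the gene passed the test, with a bar at the list median. In the fibroblast and extracellular matrix list 15 of 17 members fell, and in the inflammatory cytokine and chemokine list 10 of 12 rose.

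The comparison of Turned Cu with Turned Ti keeps the machining and changes the metal. CXCL8 rose by 11.02 ± 1.91 (again without a p by DESeq2), IDO1 by 9.86 ± 1.73, PTGS2 by 9.13 ± 1.39 and the neutrophil chemokine CXCL5 by 7.95 ± 1.51. MT1A rose by 5.26 ± 0.49 and MT2A by 6.34 ± 0.90, and ALPL stood at -5.11 ± 0.97 and COL1A2 at -4.36 ± 0.84. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4728 genes passed, 2451 higher and 2277 lower in Turned Cu. Here too the larger number turned, with 2225 higher and 2649 lower by RLE scaling and 2379 and 2896 by DESeq2. Without any 1 of the Turned Cu libraries or without Turned Ti replicate 1 or 4, between 1866 and 2258 were higher and between 2393 and 2668 lower. Of the cytokine and chemokine list 12 of 12 tested members rose (12 rose adjusted over the list alone, camera adjusted p = 7.81e-07, estimated 0.206). Interferon response genes included OAS2 at 3.42 ± 0.39, and 12 of 15 tested members rose and 3 did not pass (12 rose adjusted over the list alone, camera adjusted p = 1.94e-07, estimated 0.0889). In the T cell list 5 of 6 tested members rose and 1 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.00293, estimated 0.214), with CD5 at 3.95 ± 0.66 and CD4 at 3.21 ± 0.71. In the fibroblast and extracellular matrix list 16 of 17 tested members fell and 1 did not pass (16 fell adjusted over the list alone, camera adjusted p = 3.91e-08, estimated 0.214). In the osteoblast and bone matrix list 14 of 15 tested members fell and 1 did not pass (15 fell adjusted over the list alone, camera adjusted p = 9.31e-06, estimated 0.278).

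Several genes of matrix and granulocytes had no read in the Turned Cu libraries. Against the floor of 3 counts over the group, MGP, an inhibitor of mineralization, was at least 129.9-fold lower than in Turned Ti, MFAP4, a microfibril protein, at least 56.7-fold, and EPX, the peroxidase of eosinophils, at least 384-fold. Single libraries carried 2 of these bounds: that of MGP fell to 33.9 without Turned Ti replicate 1 (48.7 CPM) and that of EPX to 87.4 without Turned Ti replicate 4 (148 CPM). In the neutrophil list 6 of 12 tested members rose, 4 fell and 2 did not pass (6 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.154, estimated 0.81), with CSF3R at 5.51 ± 1.25. In the mitochondrially encoded list 13 of 13 tested members rose (13 rose adjusted over the list alone, camera adjusted p = 0.000285, estimated 0.499). Its level was 13.93 and 13.34 in Turned Cu replicates 2 and 4 but 11.66 and 10.58 in replicates 1 and 3, against 8.96 to 10.71 in Turned Ti. Camera with a preset correlation called 18 of 43 lists and fry 25, and with an estimated correlation the lowest adjusted p of camera was 0.0889.

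The comparison of Turned Cu with SLA Ti sets copper against the roughened titanium surface. HMOX1 stood at 1362 ± 658 CPM in Turned Cu and 17.5 ± 3.37 in SLA Ti, a rise of 6.28 ± 0.76, and MT1A and MT2A rose by 5.03 ± 0.48 and 5.30 ± 0.85. NR4A2, an immediate early nuclear receptor, rose by 4.77 ± 0.67 and BATF2, an interferon-induced transcription factor, by 4.63 ± 0.92. DNAH17, an axonemal dynein chain, went from 0.201 ± 0.0506 to 13.8 ± 4.08 CPM (6.04 ± 0.44). ADIPOQ changed by -7.04 ± 0.91 and PDGFRA by -3.30 ± 0.50. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3598 genes passed, 1776 higher and 1822 lower in Turned Cu. This balance moved both ways, to 1988 higher and 1265 lower by voom with library quality weights and to 1766 and 2341 by DESeq2. It was 1535 and 2048 by RLE scaling and 992 and 1810 without Turned Cu replicate 1. With Turned Cu replicates 2 and 4 as the whole copper group the count was 2141, and without rabbit 1 or rabbit 2 it was 1819 or 2133.

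Stress, interferon and cytokine genes rose for the most part. In the heat shock and unfolded protein list 9 of 14 tested members rose and 5 did not pass (9 rose adjusted over the list alone, camera adjusted p = 6.47e-06, estimated 0.0461), the 1 list called with an estimated correlation as well, with HSP90AA1 at 2.79 ± 0.33 and HSPA8 at 2.30 ± 0.38. In the oxidative stress list 11 of 16 tested members rose, 2 fell and 3 did not pass (11 rose and 2 fell adjusted over the list alone, camera adjusted p = 6.22e-05, estimated 0.139). In the interferon response list 11 of 15 tested members rose and 4 did not pass (12 rose adjusted over the list alone, camera adjusted p = 1.76e-07, estimated 0.115). Of the cytokine and chemokine list 7 of 12 tested members rose and 5 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.000115, estimated 0.196), with CXCL10, an interferon-induced chemokine, at 4.06 ± 0.85 and IL1RN at 3.46 ± 0.93. In the fibroblast and extracellular matrix list 14 of 17 tested members fell and 3 did not pass (15 fell adjusted over the list alone, camera adjusted p = 1.76e-07, estimated 0.191). In the osteoblast and bone matrix list 9 of 15 tested members fell and 6 did not pass (13 fell adjusted over the list alone, camera adjusted p = 3.80e-05, estimated 0.344).

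Erythroid and fat genes were lower beside copper than beside SLA Ti. In the erythroid list 7 of 10 tested members fell and 3 did not pass (9 fell adjusted over the list alone, camera adjusted p = 0.00466, estimated 0.451), with the anion exchanger SLC4A1 at -6.96 ± 1.66 and the membrane skeleton gene SPTB at -6.90 ± 1.64. In the adipocyte list 5 of 8 tested members fell and 3 did not pass (6 fell adjusted over the list alone, camera adjusted p = 0.00434, estimated 0.349). Of the neutrophil list 1 of 12 tested members rose, 4 fell and 7 did not pass (1 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.842, estimated 0.969), and the members that fell included the granule genes LCN2 at -5.78 ± 1.44, MPO at -5.74 ± 1.49 and CAMP at -5.10 ± 1.34. EPX had no read in Turned Cu and 12272 counts over the SLA Ti libraries, at least 1059-fold lower, or 195-fold without SLA Ti replicate 1. PRG3, another eosinophil granule gene, had 3 counts against 12379. SLA Ti replicate 1 stood at 425 CPM of EPX and 437 of PRG3, where the other SLA Ti libraries had at most 44.3 and 41.1. Of the proliferation genes 1 of 18 tested members rose, 6 fell and 11 did not pass (1 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.019, estimated 0.605), with the mitotic kinase PLK1 at -2.13 ± 0.49 and the replication gene MCM5 at 1.94 ± 0.34.

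The comparison of Turned Ti with Sham asks what a turned titanium implant adds to drilling, and no gene passed the test. The 6 genes of smallest p were PADI2, an enzyme that converts arginine to citrulline (2.13 ± 0.49), CNTNAP1 (-1.48 ± 0.35), DNAH17 (-2.05 ± 0.52), the muscle calcium channel RYR1 (3.60 ± 0.998), the lectin receptor CLEC4A (2.14 ± 0.60) and GAS2L3 (1.43 ± 0.42). ALPL stood at 44.1 ± 30.7 CPM in Turned Ti and 43 ± 14.3 in Sham (0.04 ± 0.77), a value whose sign turned under other settings. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 11617 genes passed, with the lowest adjusted p at 1. At an unadjusted p under 0.05 290 genes passed, where 581 would by chance, and DESeq2 and voom with library quality weights called 0 and 0.

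Several lists lay to one side by camera with its preset correlation, without any member past the test over all genes and without any list called at an estimated correlation or by fry. Skeletal muscle genes stood highest in Turned Ti replicate 1, with a list level of 4.60 (mean log2 CPM) against -0.26 to -0.06 in the other Turned Ti libraries and -0.68 to -0.01 in Sham. Of its genes 5 of 5 passed adjusted over the list alone (camera adjusted p = 8.73e-05, estimated 0.36), with RYR1 at 36.6 CPM, NEB at 85.3 and DES at 24.4 in Turned Ti replicate 1. The erythroid list lay higher (camera adjusted p = 1.23e-05, estimated 0.413), with SPTB at 3.39 ± 1.27. Its level was 3.20 and 4.28 in Turned Ti replicates 1 and 4 but 0.48 and -0.10 in replicates 2 and 3, within the -0.98 to 1.998 of Sham, and SPTB in Turned Ti replicate 3 lay below every Sham library. The macrophage list lay higher as well (camera adjusted p = 0.000699, estimated 0.275), with GPNMB at 2.26 ± 0.91, though Turned Ti replicate 4 lay within the range of Sham for the list and below every Sham library for GPNMB. T cell genes lay lower (camera adjusted p = 4.22e-05, estimated 0.275), with CD5 at -1.65 ± 0.65, as did B cell and plasma cell genes (camera adjusted p = 6.13e-05, estimated 0.262), with JCHAIN at -2.11 ± 1.005. The T cell level was -0.77 ± 0.53 in Turned Ti and -0.03 ± 0.85 in Sham, and the B cell level of Turned Ti replicate 4 lay within the range of Sham. Camera called 16 of 43 lists in all, 8 of the 37 that could be tested after thinning to equal depth and 10 of 44 without Turned Ti replicate 1 and SLA Ti replicate 3. With an estimated correlation camera called 0, and the lowest adjusted p of fry was 0.656.

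The comparison of SLA Ti with Sham asks the same of the roughened surface. Levels of inflammatory mediators were higher in SLA Ti on average, with a wide spread between libraries, and did not pass the test. CXCL8 stood at 599 ± 1154 CPM in SLA Ti and 1.24 ± 1.17 in Sham (8.92 ± 1.77), with 2329 CPM in SLA Ti replicate 3. The other genes of smallest p were OLR1, a receptor for oxidized lipoprotein (5.43 ± 1.05), the leukocyte integrin ITGAL (1.90 ± 0.38), the lectin CLEC4D (3.36 ± 0.67), PTGS2 (6.18 ± 1.24) and the autophagy gene UVRAG (4.68 ± 0.96). SLA Ti replicate 3 was the highest of its group in all 6, with 395 CPM of PTGS2 and 463 of UVRAG, where the other SLA Ti libraries had at most 59 CPM of CXCL8, 34.9 of PTGS2 and 37.8 of UVRAG. Of the context genes, ALPL had a value of -1.28 ± 0.78 and IBSP of -1.93 ± 1.09. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes passed, with the lowest adjusted p at 0.104. At an unadjusted p under 0.05 1660 genes passed (1402 higher and 258 lower), DESeq2 called 353 and voom with library quality weights 54. Without SLA Ti replicate 2 edgeR called 198 genes, without SLA Ti replicate 1 it called 32, and with the rabbit as a block and the position as a term it called 1.

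By list, myeloid and glycolytic genes lay higher in SLA Ti than in Sham and matrix genes lower. No member passed over all genes, and adjusted over the list alone 8 of 12 neutrophil genes rose (camera adjusted p = 2.30e-08, estimated 0.375), with CSF3R at 3.45 ± 1.14 and S100A12, a calcium-binding protein of granulocytes, at 3.62 ± 1.22. Likewise 14 of 19 glycolysis and hypoxia genes rose adjusted over the list alone (camera adjusted p = 3.02e-08, estimated 0.375), with the lactate exporter SLC16A3 at 3.85 ± 0.85, which passed without SLA Ti replicate 2 (4.24). Of the cytokine and chemokine genes 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.14e-05, estimated 0.375), and of the erythroid genes 9 of 10 rose (camera adjusted p = 3.10e-06, estimated 0.375), with AHSP, a haemoglobin chaperone, at 3.54 ± 1.20. The libraries did not move together. The cytokine level was 4.62 and 2.97 in SLA Ti replicates 3 and 4 but -0.05 and -0.14 in replicates 1 and 2, against -1.20 to -0.12 in Sham. The glycolysis level was 5.64 and 5.20 in replicates 3 and 4, and 4.07 and 4.12 in replicates 1 and 2, within the 3.48 to 4.29 of Sham. SLA Ti replicate 2 lay within the range of Sham for the neutrophil list and SLA Ti replicate 3 for the erythroid list. The osteoblast and bone matrix list lay lower (camera adjusted p = 5.37e-05, estimated 0.425), with SPARC at -0.996 ± 0.52, and so did the cartilage list (camera adjusted p = 0.000728, estimated 0.375), with COL2A1, the main cartilage collagen, at -5.66 ± 1.65. Camera with a preset correlation called 18 of 43 lists and with an estimated correlation 0, and the lowest adjusted p of fry was 0.107.

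The comparison of SLA Ti with Turned Ti keeps the metal and changes the surface. CXCL8 averaged 599 ± 1154 CPM in SLA Ti and 1.11 ± 0.222 in Turned Ti (9.08 ± 1.78), with 2329 CPM in SLA Ti replicate 3 and 4.64, 3.32 and 59 in replicates 1, 2 and 4. CXCL5 had a value of 7.54 ± 1.49. The other genes of smallest p were the myeloid transcription factor CEBPB (2.67 ± 0.55), PTGS2 (5.87 ± 1.21), OLR1 (4.03 ± 0.86) and the interleukin 1 decoy receptor IL1R2 (5.20 ± 1.12). SLA Ti replicate 3 was the highest of its group in each, with 127 CPM of CXCL5, 395 of PTGS2 and 113 of IL1R2, where the next highest, replicate 4, had 18.4, 34.9 and 16.3. CTSK had 152 ± 98.2 CPM in SLA Ti and 386 ± 305 in Turned Ti (-1.34 ± 0.67). None of these passed, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called, with the lowest adjusted p at 0.234. At an unadjusted p under 0.05 1048 genes passed, DESeq2 called 105 and voom with library quality weights 0. Without SLA Ti replicate 2 edgeR called 36 genes, and with the rabbit as a block it called 1.

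Adjusted over the list alone, 9 of 12 cytokine and chemokine genes (camera adjusted p = 3.59e-07, estimated 0.276) and 10 of 19 glycolysis and hypoxia genes (camera adjusted p = 1.09e-07, estimated 0.366) rose in SLA Ti against Turned Ti. Of these 8 libraries SLA Ti replicates 3 and 4 stood highest in both lists, at 4.62 and 2.97 for cytokines, against -0.14 and -0.05 in replicates 2 and 1 and -0.84 to -0.33 in Turned Ti. Adjusted in the same way 7 of 13 immediate early genes rose (camera adjusted p = 1.03e-05, estimated 0.209), with IER3 at 3.52 ± 0.83 and FOS at 3.13 ± 0.77, both past the test without SLA Ti replicate 2 (3.92 and 3.50). T cell genes lay higher, 4 of 6 adjusted over the list alone (camera adjusted p = 1.03e-05, estimated 0.209), with the kinase ZAP70 at 2.07 ± 0.58. Neutrophil genes lay higher too, 4 of 12 adjusted over the list alone (camera adjusted p = 1.19e-06, estimated 0.43), with S100A8 at 3.21 ± 1.19, though the levels of the 2 groups overlapped (3.37 to 7.17 in SLA Ti and 0.83 to 5.96 in Turned Ti). The fibroblast and extracellular matrix list lay lower (camera adjusted p = 0.000252, estimated 0.506), with the fibroblast protease FAP at -1.32 ± 0.53. Camera with a preset correlation called 16 of 43 lists and with an estimated correlation 0, and the lowest adjusted p of fry was 0.139.

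The authors' deposited table gives its own counts of differing genes at a p under 0.05 and at least a 2-fold change, without a stated test. In it 5862 genes of the authors' deposited values differed between Turned Cu and Sham, 5685 between Turned Cu and Turned Ti and 4773 between Turned Cu and SLA Ti. The authors' deposited table lists 1539 genes for SLA Ti and Sham, 811 for SLA Ti and Turned Ti and 314 for Turned Ti and Sham. By q-values under 0.05 in the authors' deposited table, without a limit on the fold, these last comparisons had 564, 18 and 1 genes.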

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

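The tests on the osteoclast and other cell lists, on SLA Ti replicate 3, and those that thin the counts or leave out ribosomal RNA and mitochondrial genes were chosen after the results were seen, and the test on transcript length before. In each group of 4 libraries the gap between the highest or lowest library and its nearest neighbour was divided by the range of the group. A ratio above the critical value of Dixon's test at 95% marked 31 of 437 groups, where chance gives about 1 in 20, or 21.9. Where all other libraries of a group have no reads of a gene, the ratio is 1 whatever the remaining value. This holds for OLR1, ATP7B, BGLAP, TEK and PRG3 below, to which the chance rate does not apply. Levels of genes and lists in these paragraphs are log2 CPM.

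Ribosomal RNA content differed within groups. Mitochondrial ribosomal RNA made up 24.3% of counts in Sham replicate 2 and 64.9% to 70.6% in the other Sham libraries (ratio 0.876). Nuclear ribosomal RNA made up 44.8% in SLA Ti replicate 4 and 1.83% to 5.23% in the other SLA Ti libraries (ratio 0.921).

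Muscle genes marked Turned Ti replicate 1 at 4.60, where the others of its group reached -0.06 (ratio 0.96). They also marked Sham replicate 1 at -0.01, with the others at up to -0.57 (ratio 0.845). ALPL was low in Turned Ti replicate 1, at 1.11 against at least 5.35 (ratio 0.847). The osteoclast list was low in Sham replicate 3, at 1.64 against at least 4.11 (ratio 0.86), together with CA2 (ratio 0.835). In that library the glycolysis and hypoxia list was high (ratio 0.933) and OLR1 had reads where the other Sham libraries had none (ratio 1).

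Sham replicate 2, the library with the fewest protein-coding counts, had the highest SPARC of its group (ratio 0.859), ATP7A (ratio 0.8292) and CLEC4A (ratio 0.834) and the lowest cell death list (ratio 0.836). Sham replicate 1 had the lowest list of matrix proteases and inhibitors (ratio 0.854) and the highest ADIPOQ (ratio 0.923). APLNR was highest in Sham replicate 4 (ratio 0.909). FOS and IL1R2 were lowest in Turned Ti replicate 3 (ratios 0.929 and 0.873), and the tricarboxylic acid cycle list was lowest in Turned Ti replicate 4 (ratio 0.90).

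Among the SLA Ti libraries the copper handling list was lowest in replicate 1 (ratio 0.892), LCN2 in replicate 2 (ratio 0.852) and PLK1 in replicate 3 (ratio 0.844). The mitochondrially encoded list was highest in replicate 4 (ratio 0.888). In Turned Cu the heat shock list was lowest in replicate 1 (ratio 0.893) and HSP90AA1 in replicate 2 (ratio 0.888). ATP7B and BGLAP had reads in Turned Cu replicate 3 alone of the Turned Cu libraries (ratio 1 each), TEK in replicate 2 alone (ratio 1) and PRG3 in replicate 4 alone (ratio 1). PTPRN was highest in replicate 3 (ratio 0.91) and the haematopoietic progenitor list in replicate 4 (ratio 0.917).

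The lower level of bone matrix and fibroblast genes in Turned Cu against Sham has several technical candidates. Their median log2 fold change was -3.73 before and -3.63 (SE 0.283) after the trend with transcript length was removed, which argues against length. The SE of medians in this paragraph come from resampling member genes and hold no spread between libraries. Of 29 members that passed, 100% still passed after thinning to equal totals over nuclear genes other than ribosomal RNA, which argues against depth. Without ribosomal RNA and mitochondrial genes 100% still passed, which argues against the weight of those genes in the scaling. Leaving them out moved the median of all genes by -0.147. Both fits scale by TMM, so an error of TMM itself was not tested. A uniform dilution by inflammatory cells would lower the genes of all other cell types in step. The osteoclast list, of a myeloid cell, had 1 member that rose and 7 that did not pass, and its median lay 2.61 (SE 1.03) above the stromal median, the endothelial list 0.54 (SE 0.81), the smooth muscle and pericyte list 0.92 (SE 0.38) and the adipocyte list 2.17 (SE 1.35). By these SE the endothelial and adipocyte lists lay within 2 SE of the stromal median and the osteoclast and smooth muscle lists did not. Members of a list move together (estimated correlation 0.521 in the osteoclast list), so resampling genes may understate the SE. With lists on both sides, dilution cannot be told apart from a loss of stromal cells or of their transcripts beside copper, and both stay open.

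SLA Ti replicate 3 reached the Turned Cu mean in CXCL8 (2329 against 2303 CPM) and passed it in IL1B (936 against 535 CPM). Over the whole cytokine list it came less near, as the next value shows. A share of Turned Cu RNA in this library would be 0.444 by the median of its cytokine genes but 0.000897 by that of MT1A, MT2A and HMOX1 (-0.0125 to 0.016), which argues against a mixed or exchanged copper sample. More granulocytes may have been present: the neutrophil list lay 0.83 above the highest other SLA Ti library, less than the 1 set as a bound, so that this cannot be told apart from higher expression per cell. The SLA surface in this rabbit stays open and untested.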

How the results depend on the processing

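Chosen after seeing the data were RLE scaling, leaving out ribosomal RNA and mitochondrial genes, thinning, leaving out libraries by their composition, and Turned Cu replicates 2 and 4 as the copper group. Genes called in Turned Cu against Sham, 4968, and against Turned Ti, 4728, stayed within 1.5 times the reported count under every alternative run. DESeq2 gave 5515 and 5275. Leaving out 1 library gave 4525 to 5102 and 4111 to 4898, and leaving out a rabbit gave 3772 to 4433 and 3596 to 4378. Against SLA Ti the count of 3598 was 2141 with Turned Cu replicates 2 and 4 alone. Leaving out 1 library gave 2659 (without SLA Ti replicate 2) to 4049 (without SLA Ti replicate 3). Leaving out a rabbit gave 1819 to 3397, lowest without rabbits 1 (1819) and 2 (2133) and highest without rabbit 3. Every fit without a rabbit held fewer libraries, so that alone does not set these rabbits apart.

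Counts of 0 depended on the method. SLA Ti against Sham gave 353 genes by DESeq2, 195 without the filter, 54 by voom with library quality weights, and 0 to 198 without 1 library (198 without SLA Ti replicate 2, 32 without SLA Ti replicate 1). SLA Ti against Turned Ti gave 105 by DESeq2, 87 without the filter and 0 to 36 without 1 library (36 without SLA Ti replicate 2). At an unadjusted p under 0.05 and a fold of at least 2 the counts were 215 for Turned Ti against Sham, 1237 for SLA Ti against Sham and 784 for SLA Ti against Turned Ti, a less strict rule. Turned Ti against Sham stayed at 0 under the other alternatives. In simulated counts DESeq2 called more planted changes than edgeR (68.4% against 44.2% of 4-fold changes in SLA Ti against Sham) and also more unchanged genes, 17.5% of its calls there against 2.22%. In SLA Ti against Turned Ti unchanged genes made up 15% against 6.98%. Otherwise the cause was not tested.

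With the rabbit as a block, SLA Ti against Turned Ti gave 1 gene and the other comparisons kept their counts within 1.5 times. With the rabbit as a block and the position as a term, SLA Ti against Sham gave 1 and SLA Ti against Turned Ti 1. The paired fit put ALPL at -0.56 in Turned Ti against Sham, where the reported value is 0.04. It left ATP7A short of the threshold in Turned Cu against Sham (1.12), and changed no other call of a named gene.

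Lists rest on the correlation assumed. With an estimated correlation camera called 0 lists in every comparison except Turned Cu against SLA Ti, where it called 1, the heat shock list. Fry, which asks whether a list moves one way, called 0 in each comparison without copper. Lists of Turned Ti against Sham went from 16 to 8 after thinning, with 37 lists tested in place of 43, to 10 without Turned Ti replicate 1 and SLA Ti replicate 3 together, and to 10 to 16 without 1 library (lowest without Sham replicate 1 or Turned Ti replicate 1). The cause was not tested.

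Among named genes the sign turned for ALPL in Turned Ti against Sham: -0.0038 by DESeq2, -0.00372 by RLE scaling and -0.27 to 0.42 without 1 library. SLC31A1 in Turned Cu against Sham was -1.33 to 0.23 without 1 library, and 0.23 without Sham replicate 2. DESeq2 put 16 further values of named genes in the SLA Ti comparisons past the threshold and ATP7A short of it, as RLE scaling did. DESeq2 gave no p for CXCL8 (10.76), IL1B (8.56) and B2M (5.22) in Turned Cu against Sham and for CXCL8 (10.93) in Turned Cu against Turned Ti, since it sets aside genes with an extreme count in 1 library, here SLA Ti replicate 3. Leaving out 1 library put 20 values past it and 13 short of it. RLE scaling moved the median of all genes by -0.14 in Turned Cu against Sham, and no filter by -0.26. Pseudocount and quantile alternatives apply to normalized values and were not run, array weights became library quality weights of voom, and the variance trend was dropped in the dispersion. At the spread and depth of these libraries edgeR's test has a limited reach where few genes change. Of planted 2-fold changes 3.3% passed in Turned Ti against Sham, and of 4-fold changes 50%. Depth was not varied in that simulation, which therefore does not tell spread from depth. Thinning to equal depth left 9383 of 11617 genes to test, and 4338, 4041 and 3011 genes called in Turned Cu against Sham, Turned Ti and SLA Ti.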

Other observations

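The test on ATOX1 was chosen after the result was seen, and the splits of the libraries before. ATOX1, the copper chaperone, was lower with copper, with a log2 fold change of -3.97 against Sham. Its gene model overlaps SPARC, which fell too. Over the 12 libraries without copper the log2 ratio of ATOX1 to SPARC had an SD of 0.279, where ATOX1 itself had 0.727. Reads of SPARC counted for ATOX1 are a candidate explanation of the lower value, and the expression of ATOX1 cannot be read from these counts.

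Granulocyte genes differed between libraries of the same group. EPX and PRG3 of eosinophils stood at 425 and 437 CPM in SLA Ti replicate 1 and at 148 and 58.6 in Turned Ti replicate 4. LCN2, MPO and CAMP of neutrophil granules stood at 640.2, 54.7 and 239 CPM in SLA Ti replicate 1, and LCN2 at 40.7 in SLA Ti replicate 2. PTGS2 stood at 395 CPM in SLA Ti replicate 3 and at 2.57 in SLA Ti replicate 2.

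Splits of the 8 libraries of each comparison into groups of 4 and 4 were tested for genes and lists. For the number of genes called with copper, the splits argue against chance, though they ignore the pairing by rabbit. In Turned Cu against Sham 1 of 35 splits, the real one, gave as many as the 4968 genes (highest other 1). Likewise 1 each gave as many as the 4728 and 3598 of Turned Cu against Turned Ti and SLA Ti (highest other 14 and 1). For Turned Ti against Sham, SLA Ti against Sham and SLA Ti against Turned Ti the real count was 0, which all 35 splits reach whatever the data, so the splits decide nothing there (highest other 0, 299 and 981). The 981 genes set SLA Ti replicates 1, 3 and 4 with Turned Ti replicate 4 against the rest, and the 299 set SLA Ti replicates 1, 3 and 4 with Sham replicate 3 against the rest, which points to a structure of the samples across groups. On the second principal component SLA Ti replicates 1, 3 and 4 and Turned Ti replicate 4 lay between 23.8 and 36.9, SLA Ti replicate 2 at -0.96 and Sham replicate 3 at 0.852, above the other Sham libraries. Each of the first 2 components sets the 2 sides of both splits apart. These components come from the same counts as the calls, so this is no independent evidence. Of the 8 splits that part every rabbit's pair as the real one does, too few for a share under 0.05, the others called at most 0 genes in each comparison.

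For lists at the preset correlation, 1 split of 35, the real one, reached the 16 of Turned Ti against Sham (highest other 14). In SLA Ti against Sham 1 split, again the real one, reached 18 (highest other 15). These splits ignore the pairing by rabbit. The splits that part every rabbit's pair are too few for a share under 0.05 (highest other 13 and 13). At an estimated correlation camera called 0 lists in both, so that no list is set apart by this. Without Sham replicate 1 or without Turned Ti replicate 1 camera called 10 lists in Turned Ti against Sham, fewer than the highest other split. Without 1 library SLA Ti against Sham kept 16 to 21 lists, above the highest other split. Because the 35 splits ignore the pairing, chance is not excluded for the number of lists in either comparison. Nor can it be excluded in SLA Ti against Turned Ti (5 splits with as many as the real 16, highest other 20). In Turned Cu against Sham (6 splits with as many as the real 20, highest other 26), Turned Cu against Turned Ti (7, real 18, highest other 23) and Turned Cu against SLA Ti (3, real 21, highest other 24) the other splits with as many set 3 copper libraries against 1 and so keep most of the copper difference, which leaves the number of lists without a say on chance. Among the splits that part every rabbit's pair the highest other counts of lists were 26 for Turned Cu against Sham, 20 for SLA Ti against Turned Ti and 23 and 24 for Turned Cu against Turned Ti and SLA Ti.

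Further comparisons in the authors' deposited table take Turned Cu replicates 2 and 4 as the copper group. At an unadjusted p under 0.05 and at least a 2-fold change they list 4790 genes against Sham, 4344 against Turned Ti and 3710 against SLA Ti, and the reason for the choice is not given in the sources used here. By q-values under 0.05 in the same table, without a limit on the fold, the counts were 4024, 2944 and 1952. By edgeR at an adjusted p under 0.05 the same copper libraries gave 3692, 3280 and 2141.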
